A study of Caenorhabditis elegans with 12 samples.

How the data were processed

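Poly(A) RNA of whole adult Caenorhabditis elegans was sequenced, per the labels, from N2 and from mir-71(n4115) mutants at day 0 and day 5 of adulthood, 3 libraries per group. Per the labels' protocols, animals were kept at 20 °C with 0.1 mg/mL 5-fluorodeoxyuridine and RNA was extracted with TRIzol.

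The deposited table used for the tests held read counts per gene and library, integers that had not been scaled. STAR 2.4.0h, DESeq2 and the build WBcel235 are named per the submitters' processing notes, without the step each served. The read counter, the gene annotation and the strand of the libraries are not given in the sources used here. The authors also deposited log2 values for the same libraries, named rlog (regularized log2 of scaled counts) per the labels of that table. All per-sample columns were used. The counts covered 46726 gene IDs, of which 43623 had a symbol in the names table and 362 had no annotation, and 20054 had 0 counts in every library.

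Everything else was computed from those values in R 4.3.3. Counts were scaled with TMM factors (0.868 to 1.17) and genes were kept by edgeR's filterByExpr, which left 16764. One model with 4 group means was fitted to all 12 libraries with edgeR 4.0.16 (quasi-likelihood, common dispersion 0.0714, 8 residual degrees of freedom). The p values of the quasi-likelihood F-test were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The 6 contrasts were day 5 against day 0 in N2 and in mutants, mutants against N2 at day 0, at day 5 and averaged over both ages, and the difference between the genotypes' changes with age (mutants minus N2). The standard error of a log2 fold change was its absolute value over the square root of F. Group levels are means of TMM-scaled CPM, and principal components used log2 CPM with a prior count of 2. Gene lists (39, each with at least 4 tested genes) were tested against all other genes with camera of limma 3.58.1, with a preset correlation of 0.01 between genes, adjusted over the lists of each contrast. Each was tested again with a correlation estimated per list and with fry. With an estimated correlation none of the 39 lists passed in any contrast, the smallest adjusted p being 0.303. Major sperm proteins, of which all 29 tested genes fell with age in N2, did not pass either. Failing that test therefore does not tell shifted lists from others here.

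Genes to name followed a rule fixed before the data were examined, as were the contrasts, tests, lists and most alternatives. Per contrast it took the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 3 log2 CPM and CPM that did not overlap between the groups (not asked of the difference between changes), with a symbol of letters and a number and at most 2 genes per symbol prefix and direction. It added up to 3 members with the smallest p from each list, and in every contrast mir-71, ppfr-1, alg-1, alg-2, daf-16, daf-2 and 11 genes that earlier publications connect with mir-71. Genes outside the rule are named as chosen after their values were seen.

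Replicate numbers were checked for pairing by the correlation of deviations from group means. Same-number correlations were 0.76, 0.66 and 0.28 between the genotypes at day 0, all above 0.1. In the other contrasts at least 1 same-number correlation was at or below 0.1, so no block entered the fits, and blocked fits are given beside the day 0 result. Scatter between replicates exceeded counting error, with a chi-square per gene of 28.7 to 313 between 2 replicates. Totals were 20.5 to 65.2 M counts per library, and 3 counts amounted to 0.045 to 0.157 CPM on the scaled totals.

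The fit was tested on simulated counts, with 16764 genes of which 200 changed. Each gene was given its real share over all libraries, the same in every group before those changes. In the real data 8729 genes were called with age in N2 and 8763 in mutants. The simulated recovery therefore holds for a small share of changed genes and does not give the recovery of the real age contrasts. For the change with age in N2, 36% of genes changed by a log2 of 1 and 66% of those changed by 2 were recovered. Of the 112 genes called there, 10 were false. The figures were 26% and 64% (5 of 95 calls false) with age in mutants and 29% and 58% (4 of 91 false) between genotypes at day 0. At day 5 they were 26% and 80% (10 of 116 false). Averaged over both ages they were 55% and 95% (10 of 160 false), and for the difference between changes 5% and 40% (1 of 46 false). In the camera test on 40 simulated sets of 30 genes, the 1 shifted set was called and no other. The simulated genes were independent, so this does not show how camera behaves on lists of correlated genes. Nor do the false calls cover differences shared by many genes, such as those among the day 0 libraries.

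Alternatives were RLE or upper-quartile factors, factors without the germline, sperm, oocyte, vitellogenin and collagen lists, no filter (26672 genes), a mean of at least 10 counts (15958 genes), DESeq2 1.42.0, limma-voom, limma on the authors' rlog values, the libraries of a contrast alone, replicate blocks, an adjusted p of 0.01 or a fold of at least 2, and each library left out in turn. For each contrast, groupings of the same libraries were counted as well, the real one included, 10 for groups of 3 and 100 drawn of 200 possible for the contrasts over both ages. Seed matches of mir-71 in transcripts were not analysed here.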

Results

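Poly(A)-selected RNA was sequenced from whole Caenorhabditis elegans adults of 2 genotypes at 2 ages. The genotypes were N2, the laboratory wild type, and mutants carrying the n4115 allele of mir-71, a microRNA gene. The ages were day 0 and day 5 of adulthood, so the 12 libraries formed 4 groups of 3. Per the labels, animals were grown at 20 °C and transferred around the final molt to plates with 0.1 mg/mL 5-fluorodeoxyuridine, an inhibitor of DNA synthesis. Total counts in N2 at day 0 were 35.6, 51.2 and 34.5 M (mega, counts per library) in replicates 1, 2 and 3. At day 5 the N2 totals were 27.1, 52 and 21.4 M. In mir-71 mutants the totals were 45.6, 65.2 and 20.5 M at day 0 and 45.5, 60.8 and 46 M at day 5. Below, CPM are counts per M counts of the scaled library, given as mean ± SD, and log2 fold changes are given ± SE, each with n = 3 libraries per group.

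Age separated the libraries more than genotype did. The first principal component of the log2 CPM held 80.8% of the variance and the next held 6.9%. Day 0 libraries spread along the first component from -153 to -75.4, with replicate 1 of both genotypes nearest to the day 5 libraries. At day 5 the genotypes lay apart on the second component, N2 between 19.7 and 57.6 and mir-71 mutants between -59.2 and -40. Vitellogenin (yolk protein) transcripts took 4.33% ± 0.71 of the counts in N2 at day 0 and 12.9% ± 2.29 at day 5 (SD, n = 3). In mir-71 mutants the shares were 2.85% ± 0.29 and 9.99% ± 4.24.

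**Figure D1:**
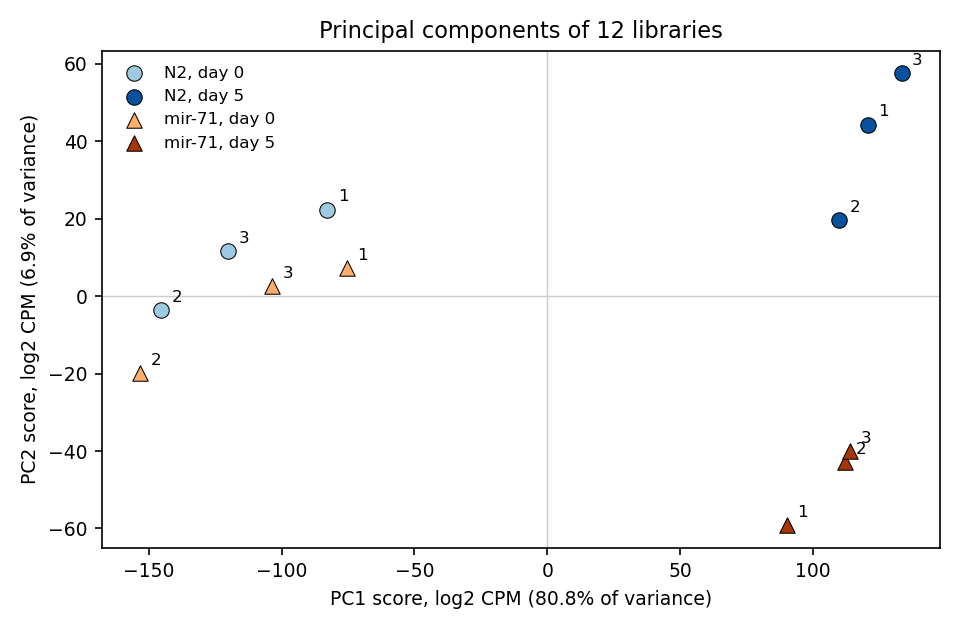
Scores of the 12 libraries on the first and second principal components of log2 CPM (16764 genes), with N2 as circles and mir-71 mutants as triangles, light for day 0 and dark for day 5, and numbers for replicates. Day 0 libraries lie between -153 and -75.4 on the first component and day 5 libraries between 90.3 and 134.

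The mir-71 gene (WBGene00003299; WBcel235 chromosome I, 9379927 to 9380020) had 0 counts in each of the 12 libraries, which allows up to 0.157 CPM (N2 day 5 replicate 3, on scaled totals), counting error only. A poly(A) library does not measure mature microRNAs, so this value checks no label. The gene lies inside an intron of 10404 bases of ppfr-1 (WBGene00008878; chromosome I, 9364099 to 9389982), which encodes a protein phosphatase 4 regulatory subunit. ppfr-1 transcripts were higher in mir-71 mutants at both ages. The level was 183 ± 9.13 CPM in N2 against 637 ± 189 CPM in mutants at day 0, and 164 ± 16 against 701 ± 108 CPM at day 5. The difference was 3.49-fold at day 0 (adjusted p = 0.00376) and 4.27-fold at day 5 (adjusted p = 0.000171), and 3.86-fold averaged over both ages (log2 1.95 ± 0.14, adjusted p = 4.81e-05, edgeR). The day 0 call was lost when the day 0 libraries were fitted alone (adjusted p = 0.167) and when both libraries numbered 3 at day 0 were left out (adjusted p = 0.181).

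Other features annotated inside that intron were chosen after their values were seen. F16A11.5, a noncoding RNA on the opposite strand (WBGene00023472; chromosome I, 9373371 to 9375824), had 51 counts over the N2 libraries and 997 over the mutant libraries. Its log2 difference was 3.33 ± 0.49 at day 0 (adjusted p = 0.0195) and 4.72 ± 0.57 at day 5 (adjusted p = 0.000511). F16A11.8, beside mir-71, had 2 counts in N2 and 107 in the mutants, cel-mir-2 4 and 37, F16A11.12 0 and 42, and F16A11.13 8 and 14. F16A11.6 had 1 and 0, and anr-25 had 0 in every library. The antisense transcript anr-20, which overlaps a ppfr-1 exon, had 353 and 384 counts and did not pass the test. The strand of the libraries is not given in the sources used here, so counts of overlapping features are uncertain. Of 42 tested genes within 100 kb outside ppfr-1, 4 passed the test averaged over both ages, rpoa-2 at -0.40, F30A10.13 at -1.2, M04C9.4 at 1.09 and twk-29 at 1.09, also chosen after their values were seen.

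**Figure D2:**
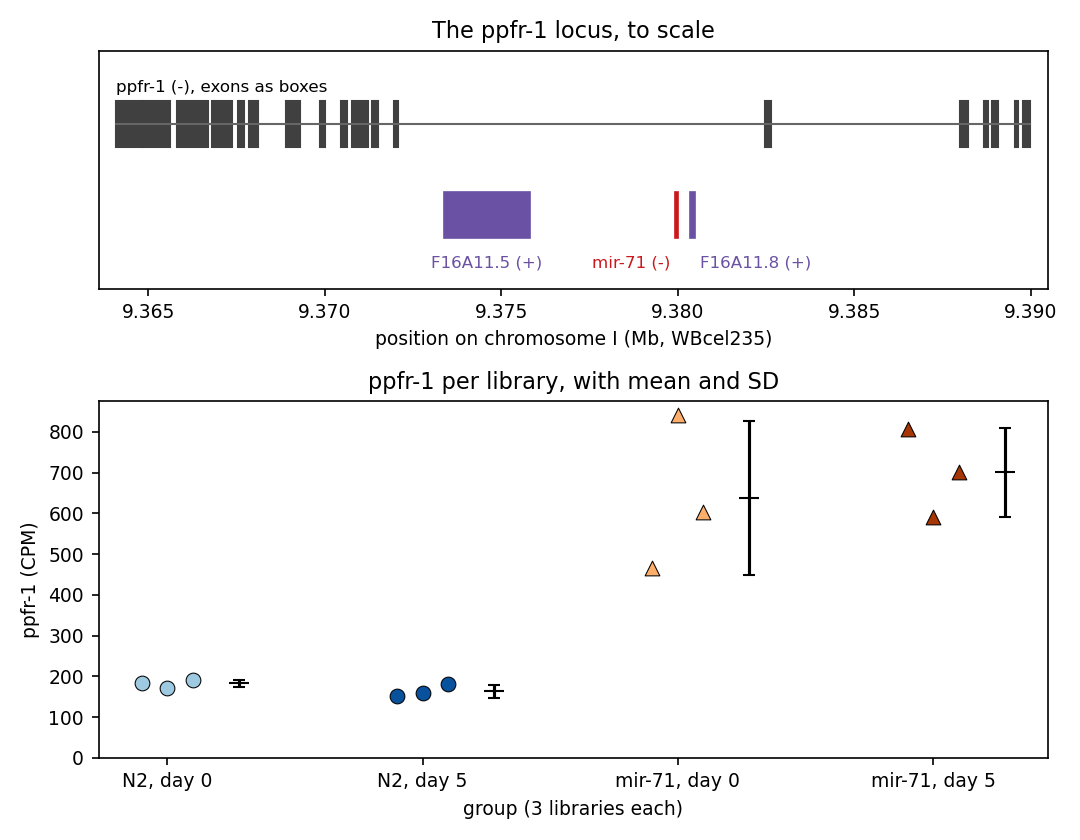
Top, ppfr-1 exons (boxes), mir-71, F16A11.5 and F16A11.8 on chromosome I in Mb of WBcel235, with strands in brackets. Bottom, ppfr-1 in CPM per library (points) with mean and SD per group of 3; all 6 mutant libraries lie above all 6 N2 libraries.

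The change from day 0 to day 5 in N2 is called the change with age for short. Animals were moved to the drug around the final molt, so age, time since the molt and time on the drug rose together. Their effects cannot be told apart in these libraries. The genes far-3, lys-7, mtl-1 and ins-7 rose, and most tested sperm, collagen, muscle and pharynx genes fell. With an estimated correlation camera called none of these lists (adjusted p of 0.512 to 0.555), nor any of the 39 lists. Of 16764 genes, 3998 rose and 4731 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Large rises included far-3, a fatty acid and retinol binding protein gene, from 9.11 ± 3.18 to 591 ± 147 CPM (log2 6.02 ± 0.50, adjusted p = 2.99e-06). The lysozyme gene lys-7 rose from 25.5 ± 7.01 to 992 ± 350.3 CPM (log2 5.28 ± 0.40, adjusted p = 2.05e-06). The metallothionein gene mtl-1 rose from 0.649 ± 0.309 to 62.5 ± 8.01 CPM (log2 6.56 ± 0.41, adjusted p = 9.52e-07), and the insulin-like peptide gene ins-7 from 3.07 ± 0.114 to 20.8 ± 4.09 CPM (log2 2.76 ± 0.21, adjusted p = 2.07e-06). Further rises were those of ugt-31 (log2 3.9), lgmn-1 (3.62), col-95 (3.33), clec-85 (3.29), drd-50 (3.27) and cup-16 (3.2).

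Sperm and cuticle genes held the deepest falls in N2. All 29 tested major sperm protein genes fell, with a median log2 fold change of -8.01 (camera adjusted p = 2.42e-17; adjusted p = 0.512 with an estimated correlation) and 29 adjusted over the list alone. msp-76 changed by -8.81 ± 0.68 and msp-36 by -8.4 ± 0.54. Of 33 other sperm genes, 29 fell, 2 rose and 2 did not pass, the same counts as adjusted over the list alone, with a median of -5.21 (adjusted p = 2.75e-10; adjusted p = 0.525 with an estimated correlation). ssq-2 changed by -8.35 ± 0.63 and ssq-4 by -8.18 ± 0.64. Among 148 cuticle collagen genes, 116 fell, 11 rose and 21 did not pass (117 and 12 adjusted over the list alone). Their median was -3.8 (adjusted p = 1.32e-12; adjusted p = 0.525 with an estimated correlation). col-139 changed by -9.76 ± 1.00, col-81 by -9.55 ± 1.01 and the adult collagen gene col-19 by -4.4 ± 0.28. On the authors' rlog values the medians were -4.9 for major sperm proteins, -3.29 for other sperm genes and -2.19 for collagens. Members of the msp, ssq, nsph and col families share sequence, so reads assigned to single members are uncertain. These lists also differed among the day 0 libraries. In N2 replicate 1 and mutant replicates 1 and 3 against the other 3 day 0 libraries, 22 of 29 major sperm protein genes, 28 of 33 other sperm genes and 65 of 148 collagen genes were lower.

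Most tested muscle, pharynx and respiratory chain genes fell in N2. Of 34 body wall muscle genes, 31 fell, 1 rose and 2 did not pass (31 and 1 adjusted over the list alone), with a median of -2.41 (adjusted p = 6.2e-12; adjusted p = 0.512 with an estimated correlation). The troponin gene unc-27 changed by -3.1 ± 0.15 and the myosin light chain gene mlc-3 by -2.9 ± 0.17. In the pharynx list 13 of 16 genes fell and 3 did not pass (13 fell adjusted over the list alone), with a median of -2.997 (adjusted p = 0.00481; adjusted p = 0.555 with an estimated correlation). The pharyngeal myosin gene myo-1 changed by -3.37 ± 0.39. On the authors' rlog values the medians were -1.62 for muscle and -1.78 for pharynx. Among the 6 day 0 libraries, 26 of 34 muscle genes and 8 of 16 pharynx genes were lower in the same 3 libraries named above. Respiratory chain genes fell in 34 of 37 cases (34 adjusted over the list alone), with a median of -0.69 (adjusted p = 4.13e-07; adjusted p = 0.512 with an estimated correlation), as for the ATP synthase subunit genes asg-2 at -1.88 and asb-2 at -1.79. Of 39 neuronal genes, 20 fell, 2 rose and 17 did not pass (22 and 2 adjusted over the list alone), with a median of -0.70 (adjusted p = 0.00592; adjusted p = 0.746 with an estimated correlation). The touch neuron tubulin genes mec-7 and mec-12 changed by -1.64 and -1.52.

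Most tested oocyte and DNA replication genes rose in N2. Of 26 oocyte and eggshell genes, 25 rose and 1 did not pass (25 adjusted over the list alone), with a median of 1.2 (adjusted p = 2.75e-10; adjusted p = 0.512 with an estimated correlation). The RNA-binding protein genes puf-5 and puf-11 changed by 1.8 and 1.44. DNA replication and cell cycle genes rose in 33 of 36 cases (33 adjusted over the list alone), with a median of 0.78 (adjusted p = 2.75e-10; adjusted p = 0.512 with an estimated correlation), among them the thymidylate synthase gene tyms-1 at 2.43 and pcn-1, which encodes PCNA, at 1.24. The germline and meiosis list was not called, with 8 genes up, 6 down and 16 not passing (8 and 6 adjusted over the list alone); its median of 0.12 turned to -0.02 with upper-quartile factors. Yolk genes moved both ways as counted, with vit-5 at 2.6 ± 0.31 and vit-2 at 2.09 ± 0.30 against vit-1 at -1.98 ± 0.37. The read counter is not given in the sources used here, so how reads were assigned among single vit genes is uncertain.

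Of 59 cytochrome P450 genes, 28 rose, 3 fell and 28 did not pass (28 and 3 adjusted over the list alone), with a median of 0.63 (adjusted p = 9.8e-05; adjusted p = 0.476 with an estimated correlation); cyp-14A5 was at 3.43. Lysozyme and antimicrobial peptide genes rose in 39 and fell in 20 of 86 cases (41 and 20 adjusted over the list alone), with a median of 0.62 (adjusted p = 0.00807; adjusted p = 0.512 with an estimated correlation). Of 24 genes known as induced by the transcription factor DAF-16, 14 rose, 3 fell and 7 did not pass (14 and 3 adjusted over the list alone), with a median of 1.00 (adjusted p = 0.00575; adjusted p = 0.512 with an estimated correlation). nnt-1 was at 2.37 and cdr-2 at 1.85. The C-type lectin list, 49 up and 27 down of 133 (49 and 27 adjusted over the list alone), was not called, and its median (0.40) and mean (-0.08) differed in sign. Among the 11 genes named in the literature for mir-71, 4 rose, 3 fell and 4 did not pass (4 and 3 adjusted over the list alone), with cdc-25.1 at 0.78, tir-1 at 0.88 and nsy-1 at -0.79. Of those 7 calls, 4 were lost without N2 day 0 replicate 2, and each of them also without other single libraries: age-1 without either of 2 (adjusted p up to 0.0819), hbl-1 without any 1 of 4 (0.0936), lin-42 without any 1 of 8 (0.127) and unc-31 without any 1 of 9 (0.183). With upper-quartile factors the median of all genes was -0.22 instead of -0.09; none of the 18 lists called in N2 changed direction under the scaling methods tried. Of 138 named genes past the threshold, 133 kept their call without each library in turn.

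**Figure D3:**
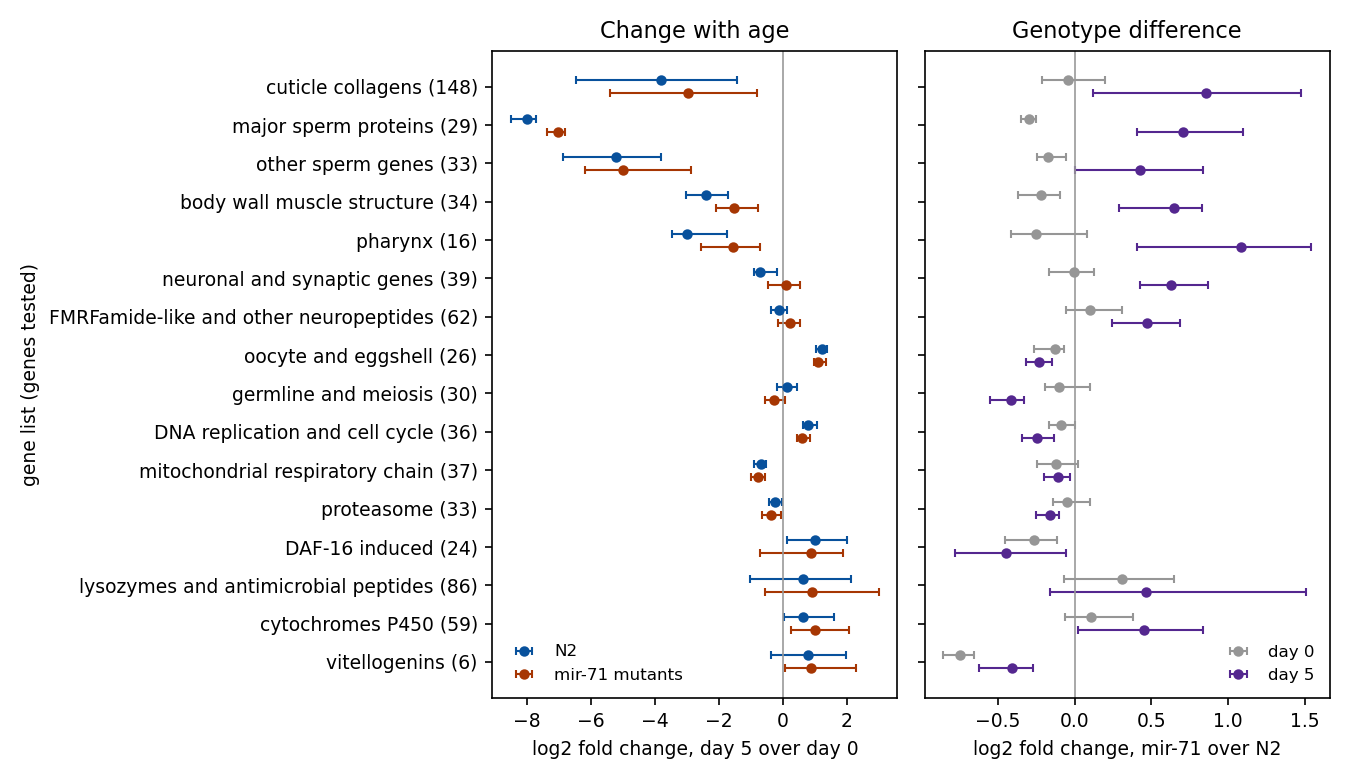
Median log2 fold change of 16 gene lists (points) with quartiles (bars), left for day 5 over day 0 in N2 and mir-71 mutants and right for mir-71 mutants over N2 at each age; the number of genes tested is in brackets. Collagen medians with age were -3.8 and -2.97, and the muscle median between genotypes was 0.65 at day 5; no list called in the test changed direction between scaling methods.

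The same comparison was made in mir-71 mutants, with the same limits on age and drug. Mature mir-71 was not measured, and ppfr-1 transcripts were higher in these animals. Changes therefore cannot be assigned to loss of mir-71 alone. The genes lys-7, ins-7 and nlp-34 rose, and most tested major sperm protein, collagen, muscle and respiratory chain genes fell, in lists with an adjusted p = 0.62 with an estimated correlation. Here 4175 genes rose and 4588 fell. The gene lys-7 reached 1802 ± 678 CPM (log2 6.25 ± 0.42, adjusted p = 1.36e-06). The insulin-like peptide gene ins-7 rose from 3.75 ± 1.00 to 143 ± 17.4 CPM (log2 5.28 ± 0.23, adjusted p = 1.45e-07). nlp-34, of a family of antimicrobial peptide genes, rose from 2.75 ± 1.84 to 141 ± 57.2 CPM (log2 5.75 ± 0.57, adjusted p = 8.3e-06). Other rises were srlf-34 (5.66), far-3 (4.58), cyp-14A5 (4.44), drd-50 (4.39) and clec-146 (4.23). Large falls were col-81 (-8.27), col-139 (-8.24), ssq-2 (-7.51), msp-76 (-7.39), nsph-3.2 (-7.2) and nspd-1 (-6.67), in families whose members share reads.

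In the mutants all 29 major sperm protein genes fell (29 adjusted over the list alone), with a median of -7.02 (adjusted p = 7.67e-18; adjusted p = 0.62 with an estimated correlation). Of 148 collagens, 107 fell, 9 rose and 32 did not pass (107 and 12 adjusted over the list alone), with a median of -2.97 (adjusted p = 5.49e-10; adjusted p = 0.62 with an estimated correlation). Muscle genes fell in 29 of 34 cases (29 adjusted over the list alone), with a median of -1.54 (adjusted p = 1.9e-08; adjusted p = 0.62 with an estimated correlation); unc-27 was at -2.45 and tnt-2 at -3.65. On the authors' rlog values the medians were -4.46 for major sperm proteins, -1.89 for collagens and -1.05 for muscle. These lists were among those that differed between the day 0 libraries, as given for N2. Respiratory chain genes fell in 33 of 37 cases (33 adjusted over the list alone), with a median of -0.77 (adjusted p = 3.77e-08; adjusted p = 0.62 with an estimated correlation). Proteasome genes fell in 20 of 33 (21 adjusted over the list alone), with a median of -0.38 (adjusted p = 0.00169; adjusted p = 0.647 with an estimated correlation), and mitochondrial stress genes in 8 of 15 (8 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.0206; adjusted p = 0.397 with an estimated correlation). The mitochondrial chaperonin gene hsp-60 was at -2.08 ± 0.18. The neuronal list was not called in the mutants, with 7 genes up, 5 down and 27 not passing (7 and 5 adjusted over the list alone).

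Rises in mutants covered 24 of 26 oocyte and eggshell genes (24 adjusted over the list alone), with a median of 1.09 (adjusted p = 3.85e-08; adjusted p = 0.62 with an estimated correlation). Of 36 DNA replication genes, 30 rose and 6 did not pass (30 adjusted over the list alone), with a median of 0.61 (adjusted p = 1.02e-06; adjusted p = 0.62 with an estimated correlation). Cytochrome P450 genes rose in 33 and fell in 4 of 59 cases (35 and 4 adjusted over the list alone), with a median of 1.00 (adjusted p = 1.49e-05; adjusted p = 0.303 with an estimated correlation). Lysozyme and antimicrobial peptide genes rose in 45 and fell in 20 of 86 (46 and 20 adjusted over the list alone), with a median of 0.90 (adjusted p = 0.00152; adjusted p = 0.62 with an estimated correlation); cnc-2 was at 5.79. Among the 11 genes named in the literature for mir-71, 4 rose, 1 fell and 6 did not pass (4 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0998). hbl-1 changed by 2.16 ± 0.27, tir-1 by 1.6 ± 0.25 and cdc-25.1 by 0.68 ± 0.13. lin-42 changed by -1.89 ± 0.54, a call lost without mutant day 0 replicate 2 (adjusted p = 0.0619), and pha-4 by 0.69 ± 0.22, lost without any of 4 libraries (up to 0.081). The argonaute genes alg-1 (0.40, adjusted p = 0.211) and alg-2 (0.28, adjusted p = 0.234) did not pass. Of 134 named genes past the threshold, 130 kept their call without each library in turn.

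Across the 16764 genes, log2 changes with age in N2 and in mutants correlated at 0.927 (Pearson) and 0.843 (Spearman), with an orthogonal slope of 0.929; genes are not independent replicates. Of the genes that rose in N2, 2956 also rose in mutants, where 995.7 were expected if independent, and 10 fell. Of those that fell in N2, 3679 also fell in mutants, where 1295 were expected, and 25 rose.

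At day 0 the genotypes differed in few genes. Apart from ppfr-1, the infection response gene irg-5 was higher in mutants, at 35.3 ± 7.51 against 10.3 ± 1.27 CPM (log2 1.77 ± 0.21, adjusted p = 0.00429). pes-8 was at 20.8 ± 9.49 against 5.9 ± 1.38 CPM (log2 1.82 ± 0.30, adjusted p = 0.0403). In all, 12 genes were higher and 10 lower in mutants by edgeR. Vitellogenin genes had a negative difference in 6 of 6 cases, none passing singly, with a median of -0.75 (camera adjusted p = 9.68e-05; adjusted p = 0.863 with an estimated correlation). Lysozyme and antimicrobial peptide genes had a median of 0.31 (adjusted p = 0.00151; adjusted p = 0.863 with an estimated correlation), and 2 of 86 were higher adjusted over the list alone. The other 9 called lists were shifted downward in mutants (adjusted p of 0.863 to 0.942 with an estimated correlation), and each lost its call without at least 1 library. For muscle, with a median of -0.22 (adjusted p = 0.000704; adjusted p = 0.942 with an estimated correlation), the call was lost without N2 day 0 replicate 3 or mutant day 0 replicate 1 (adjusted p = 0.776 for the latter), and 26 of its 34 genes differed along the spread of the day 0 libraries.

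None of daf-16 (-0.17), daf-2 (-0.35), alg-1 (-0.20), alg-2 (-0.07) and hbl-1 (-0.87) passed at day 0. Replicate numbers paired the day 0 libraries of the genotypes, and with a replicate block within each age 73 genes passed (40 higher, 33 lower), among them all 22. With a block in the day 0 libraries alone 60 passed, sharing 21, and with a replicate block 17 lists were called instead of 11. Fitting the day 0 libraries alone gave 0 genes by edgeR, with 536 at an unadjusted p under 0.05, whereas all libraries gave 62 genes by DESeq2, 18 by limma-voom and 28 by limma on the authors' rlog values. Voom's split was 8 higher and 10 lower. The count was 11, 8 or 5 without N2 day 0 replicate 1, 2 or 3, 14 without mutant day 0 replicate 1 and 6 without mutant day 0 replicate 3. irg-5 lost its call without N2 day 0 replicate 3 (adjusted p = 0.0549), and pes-8 without any of 11 libraries (up to 0.214).

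At day 5 the genotypes differed widely. The peptide genes nlp-34 and ins-7 were among the genes higher in mir-71 mutants, and mtl-1, mtl-2, hex-1 and asp-14 among those lower. Of 16764 genes, 1279 were higher and 519 lower, 71.1% higher by edgeR with TMM. nlp-34 was at 141 ± 57.2 CPM in mutants and 6.56 ± 0.87 CPM in N2 (log2 4.42 ± 0.53, adjusted p = 0.000511). ins-7 was 6.88-fold higher, at 143 ± 17.4 against 20.8 ± 4.09 CPM (log2 2.78 ± 0.20, adjusted p = 3.92e-05). The transthyretin-like gene ttr-32 was at 93 ± 43.6 against 9.37 ± 2.4 CPM (log2 3.3 ± 0.34, adjusted p = 0.000285). tatn-1, a tyrosine aminotransferase gene, was at 80.5 ± 16.8 against 12.7 ± 1.91 CPM (log2 2.67 ± 0.31, adjusted p = 0.000449). Also higher were ttr-14 (3.53), srlf-34 (3.46), nlp-26 (2.74), fip-5 (2.7) and mua-6 (2.38).

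mtl-1 was 45.1-fold lower in mutants at day 5, at 1.39 ± 0.383 against 62.5 ± 8.01 CPM (log2 -5.5 ± 0.39, adjusted p = 3.92e-05). The other metallothionein gene, mtl-2, was at 13.7 ± 3.83 against 81.7 ± 19.4 CPM (log2 -2.58 ± 0.32, adjusted p = 0.000595). hex-1, a hexosaminidase gene, was at 23.9 ± 0.591 against 98.5 ± 21.1 CPM (log2 -2.04 ± 0.15, adjusted p = 3.92e-05), and the aspartyl protease gene asp-14 at 7.07 ± 1.45 against 51.4 ± 1.46 CPM (log2 -2.87 ± 0.27, adjusted p = 0.000157). The gut esterase gene ges-1 was at -2.23 ± 0.26, clec-66 at -2.93 ± 0.47 and pud-3 at -2.54 ± 0.42. The intestine list as a whole had a median of 0.65 and was not called, so ges-1 does not stand for gut genes at large. Of 24 DAF-16 induced genes, 6 were lower, 1 was higher and 17 did not pass (8 and 1 adjusted over the list alone). The list had a median of -0.45 (camera adjusted p = 0.000956; adjusted p = 0.732 with an estimated correlation), with dod-6 at -1.43. daf-16 itself was at -0.08 (adjusted p = 0.787) and daf-2 at -0.48 (adjusted p = 0.21).

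Several lists were shifted upward in day 5 mutants by camera, though a minority of the genes in each passed singly; all had an adjusted p = 0.777 with an estimated correlation. Of 86 lysozyme and antimicrobial peptide genes, 24 were higher, 6 lower and 56 did not pass (31 and 8 adjusted over the list alone), with a median of 0.47 (adjusted p = 0.0018; adjusted p = 0.777 with an estimated correlation). fipr-21 was at 3.11 ± 0.33 and cnc-6 at 4.51 ± 0.51. Neuronal genes were higher in 10 of 39 cases (24 adjusted over the list alone), with a median of 0.63 (adjusted p = 3.03e-08; adjusted p = 0.777 with an estimated correlation); rab-3, a synaptic vesicle GTPase gene, was at 0.99 and lost its call without N2 day 5 replicate 1 (adjusted p = 0.0502). Neuropeptide genes were higher in 7 and lower in 1 of 62 (18 and 2 adjusted over the list alone), with a median of 0.47 (adjusted p = 2.04e-05; adjusted p = 0.777 with an estimated correlation). Of 34 muscle genes, 13 were higher and 21 did not pass (19 higher adjusted over the list alone), with a median of 0.65 (adjusted p = 3.71e-05; adjusted p = 0.777 with an estimated correlation). unc-87 was at 0.96 and lost its call without N2 day 5 replicate 3 (adjusted p = 0.051). Pharynx genes were higher in 4 of 16 (5 adjusted over the list alone), with a median of 1.08 (adjusted p = 0.019; adjusted p = 0.777 with an estimated correlation). Collagens were higher in 20 of 148 (22 higher and 1 lower adjusted over the list alone), with a median of 0.86 (adjusted p = 0.00197; adjusted p = 0.777 with an estimated correlation), as for col-140 (1.93) and col-178 (1.88). Insulin-like peptide genes were higher in 4 of 31 (4 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.0163, and 0.777 with an estimated correlation), with ins-4 at 2.47. On the authors' rlog values the medians were smaller, at 0.24 for lysozymes and antimicrobial peptides, 0.38 for neuronal genes and 0.29 for neuropeptides. They were 0.36 for muscle, 0.45 for pharynx, 0.19 for collagens and 0.29 for insulin-like peptides.

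Germline and meiosis, DNA replication and oocyte lists were shifted downward in day 5 mutants by camera (adjusted p = 0.777 with an estimated correlation), and sperm lists were not. Major sperm proteins had a median of 0.71 (28 of 29 positive, camera adjusted p = 0.109) and other sperm genes 0.43 (24 of 33 positive, adjusted p = 0.52), neither list called and no member passing. On the authors' rlog values these medians were 0.12 and 0.0988. The major sperm protein medians for the change with age were -8.01 in N2 and -7.02 in mutants, so these are differences between the low levels left at day 5. Of 30 germline and meiosis genes, 6 were lower and 24 did not pass (20 lower adjusted over the list alone), with a median of -0.42 (adjusted p = 1.02e-08; adjusted p = 0.777 with an estimated correlation). fbf-1, a regulator of germline stem cells, was at -0.87 and lost its call without any of 4 libraries (adjusted p up to 0.114). DNA replication genes had a median of -0.25 with 1 of 36 lower and none adjusted over the list alone (adjusted p = 1.39e-05; adjusted p = 0.777 with an estimated correlation). Oocyte and eggshell genes had a median of -0.23, none of the 26 passing either way (adjusted p = 0.0019; adjusted p = 0.777 with an estimated correlation). Other small RNA pathway genes were lower in 6 and higher in 1 of 42 (8 and 1 adjusted over the list alone), with a median of -0.28 (adjusted p = 1.88e-05; adjusted p = 0.777 with an estimated correlation). Of the 11 genes named in the literature for mir-71, 10 did not pass and none passed adjusted over the list alone. Of these, tir-1 was at 0.85 (adjusted p = 0.0461), a call lost without any of 9 libraries (adjusted p up to 0.178). The argonaute gene alg-1 was at 0.64 (adjusted p = 0.126). The miRNA pathway list as a whole was shifted downward, with a median of -0.24 (camera adjusted p = 0.0123). That call was lost without N2 day 5 replicate 3 or mutant day 5 replicate 1 (up to 0.0765). Averaged over both ages the list had a median of -0.21 (camera adjusted p = 0.00108), a call kept without each library in turn. Neither call stayed with an estimated correlation.

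The day 5 split of 1279 and 519 rested on the scaling: RLE factors gave 1113 and 825 (57.4% higher), DESeq2 1540 and 1301 (54.2%) and the authors' rlog values 1296 and 946 (57.8%). A fit of the day 5 libraries alone gave 2722 genes (1999 and 723). The count fell from 1798 to 760 or 608 without N2 day 5 replicate 1 or 3, to 628 without mutant day 5 replicate 1 and to 1179 without mutant day 5 replicate 2; 51 of 94 named genes past the threshold kept their call without each library in turn.

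Averaged over both ages, the genotype comparison gave the mean of the differences at day 0 and day 5. ppfr-1, irg-5, pes-8 and nlp-29 were higher in mutants, and mtl-1 and mtl-2 were lower. In all, 679 genes were higher and 195 lower. irg-5 differed by 1.57 ± 0.15 (adjusted p = 0.000179), pes-8 by 1.82 ± 0.21 (adjusted p = 0.000697) and nlp-29 by 1.73 ± 0.24 (adjusted p = 0.0017). Others higher were ttr-32 (1.9), ttr-33 (1.58), fip-6 (1.42), nlp-28 (1.4), the hydroxyanthranilate dioxygenase gene haao-1 (1.27) and the bZIP factor gene zip-10 (1.07). mtl-1 was lower at -2.9 ± 0.27 (adjusted p = 0.000179), with mtl-2 at -1.39, dod-6 at -0.89, pud-3 at -1.77, ges-1 at -1.48 and npa-1 at -0.84. The values of mtl-1, mtl-2, ins-7, ttr-32 and ttr-33 averaged unlike differences at the 2 ages, as their change with age differed by genotype.

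Among lists, vitellogenins had a median of -0.63 (4 of 6 lower adjusted over the list alone; camera adjusted p = 0.000562; adjusted p = 0.787 with an estimated correlation). Lysozyme and antimicrobial peptide genes were higher in 18 and lower in 1 of 86 (27 and 5 adjusted over the list alone), with a median of 0.39 (adjusted p = 9.07e-05; adjusted p = 0.662 with an estimated correlation). DAF-16 induced genes were lower in 4 of 24 (7 lower and 1 higher adjusted over the list alone), with a median of -0.35 (adjusted p = 0.000203; adjusted p = 0.451 with an estimated correlation). Germline and meiosis genes were lower in 2 of 30 (15 adjusted over the list alone), with a median of -0.25 (adjusted p = 4.2e-07; adjusted p = 0.749 with an estimated correlation). Neuronal genes had a median of 0.27 with 1 of 39 higher (9 adjusted over the list alone, camera adjusted p = 1.94e-05, and 0.836 with an estimated correlation). The last 3 lists averaged unlike medians at day 0 and day 5. These were -0.27 and -0.45 for DAF-16 induced genes, -0.0989 and -0.42 for germline and meiosis, and -0.00692 and 0.63 for neuronal genes. The split was 1007 and 713 (58.5% higher) by DESeq2 and 669 and 350 (65.7%) by limma on the rlog values, against 77.7%. As replicate numbers paired the day 0 libraries, a replicate block within each age was fitted too and gave 2455 genes (1623 and 832), among them all 874. That fit also blocked the day 5 libraries, where same-number correlations between the genotypes were 0, -0.01 and 0.19. Its count therefore cannot be credited to the day 0 pairing alone. The count of 874 fell to 455 without mutant day 5 replicate 1, to 467 and 491 without N2 day 5 replicates 3 and 1, and to 505 and 558 without N2 day 0 replicates 1 and 3. Without both day 0 libraries numbered 3 it was 298. Of 69 named genes past the threshold, 45 kept their call without each library in turn. All 12 genes higher at day 0 were also higher at day 5, where 0.916 were expected if independent, and 6 of the 10 lower ones were lower, where 0.31 were expected. Genotype differences at both ages correlated at 0.252 (Pearson) and 0.199 (Spearman) across genes, which are not independent replicates. That correlation was 0.0513 without mutant day 0 replicate 2 and 0.118 without N2 day 0 replicate 1.

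The last comparison tested whether the change with age differed by genotype. ins-7 rose more with age in mir-71 mutants than in N2, mtl-1 rose less in mutants than in N2, and hex-1 rose in N2 (log2 1.16) and fell in mutants (-0.79). The difference in log2 change was 2.52 ± 0.29 for ins-7 (adjusted p = 0.00517), -5.18 ± 0.54 for mtl-1 (adjusted p = 0.00501) and -1.95 ± 0.21 for hex-1 (adjusted p = 0.00501). hex-1 went from 44.2 ± 4.43 to 98.5 ± 21.1 CPM in N2 and from 41.4 ± 2.56 to 23.9 ± 0.591 CPM in mutants. mtl-1 went from 0.566 ± 0.245 to 1.39 ± 0.383 CPM in mutants (log2 1.38), against a rise to 62.5 ± 8.01 CPM in N2 (log2 6.56). In all, 76 genes had a more positive and 17 a more negative change in mutants. Larger differences were those of nlp-34 (4.34 ± 0.72, adjusted p = 0.0265), ttr-32 (2.8 ± 0.45, adjusted p = 0.0252), fipr-21 (2.61 ± 0.44, adjusted p = 0.0265) and tatn-1 (2.58 ± 0.42, adjusted p = 0.0261). fipr-21 went from 81.5 ± 26.6 to 18.8 ± 1.91 CPM in N2 and from 116 ± 31.5 to 163 ± 61.3 CPM in mutants. On the negative side, mtl-2 was at -2.37 ± 0.44 (adjusted p = 0.0366), asp-14 at -2.04 ± 0.35 (adjusted p = 0.0267) and the glutathione transferase gene gst-4 at -1.3 ± 0.22 (adjusted p = 0.0265). Of the 12 fits without 1 library, nlp-34 lost its call in 6 (highest 0.0879, without N2 day 5 replicate 3), ttr-32 in 7 (0.0865, without N2 day 5 replicate 3), fipr-21 in 9 (0.0879, without N2 day 5 replicate 3) and tatn-1 in 6 (0.0865, without N2 day 5 replicate 3), with the highest adjusted p in brackets. On the negative side the numbers were mtl-2 in 8 (0.101, without N2 day 5 replicate 1), asp-14 in 7 (0.0879, without N2 day 5 replicate 3) and gst-4 in 7 (0.0865, without N2 day 5 replicate 3).

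**Figure D4:**
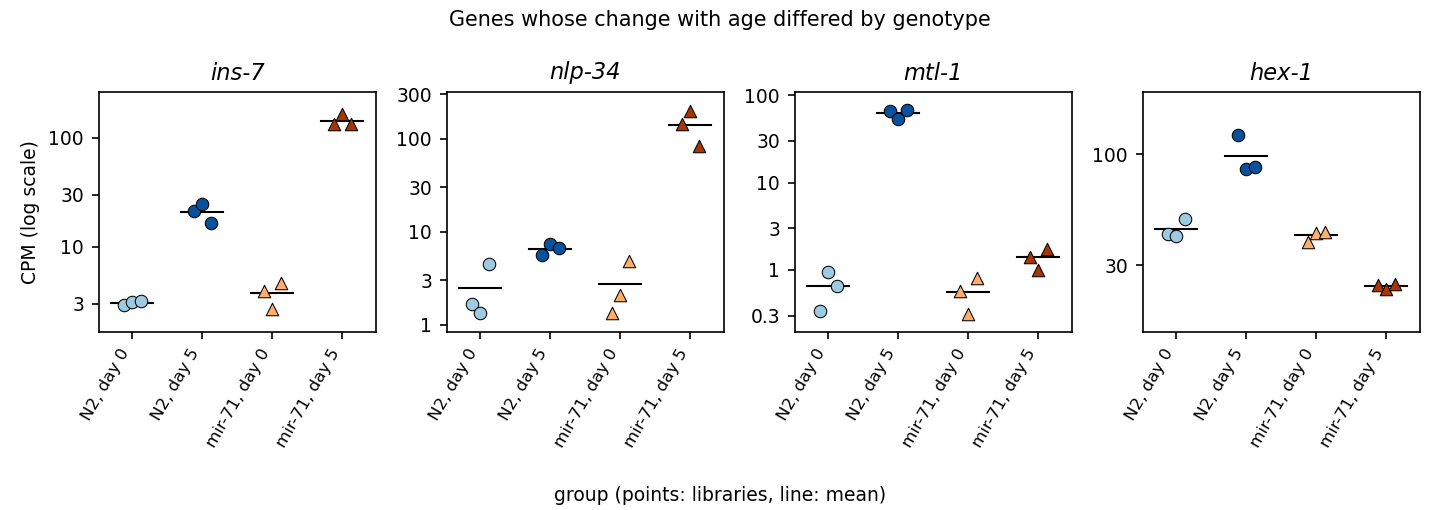
CPM per library on a log axis for ins-7, nlp-34, mtl-1 and hex-1 in the 4 groups of 3 libraries, with points for libraries and lines for group means. At day 5 ins-7 averaged 143 CPM in mir-71 mutants and 20.8 CPM in N2, and mtl-1 averaged 1.39 and 62.5 CPM.

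Muscle genes had a more positive change with age in mutants, by a median of 0.83 (camera adjusted p = 8.33e-09; adjusted p = 0.793 with an estimated correlation), with 17 of 34 adjusted over the list alone and 34 not passing over all genes. Neuronal genes differed by a median of 0.70 (4 of 39 adjusted over the list alone; adjusted p = 8.33e-09; adjusted p = 0.793 with an estimated correlation). For pharynx genes the median was 1.03 (1 of 16 adjusted over the list alone; adjusted p = 0.00531; adjusted p = 0.793 with an estimated correlation). Germline and meiosis genes had a median of -0.35, none of the 30 passing over all genes or over the list alone (adjusted p = 9.7e-07; adjusted p = 0.793 with an estimated correlation). These 4 of 13 called lists kept their call without each library in turn. With fry none of the 39 lists passed for the difference between changes (smallest adjusted p = 0.224). Muscle and pharynx genes also differed among the day 0 libraries that enter this contrast. ppfr-1 (0.29, adjusted p = 0.666), hbl-1 (1.4, adjusted p = 0.131), alg-1 (0.84, adjusted p = 0.324) and tir-1 (0.72, adjusted p = 0.373) did not pass.

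The count of 93 genes was 531 by DESeq2 (355 and 176, 66.9% positive against 81.7%), 162 on the rlog values (114 and 48, 70.4%), 32 by limma-voom and 245 with no filter on low counts. Blocks by replicate number were fitted since the numbers paired the day 0 libraries. They also covered day 5, where the numbers did not pair the genotypes. With the number as a block the count was 233 (179 and 54), and with a block within each age 1045 (817 and 228), all 93 among them each time. Without both day 0 libraries of the same number it was 68, 234 and 7 for numbers 1, 2 and 3. It was 34 and 16 without N2 day 0 replicates 2 and 3, 9, 46 and 10 without N2 day 5 replicates 1, 2 and 3, 60, 463 and 27 without mutant day 0 replicates 1, 2 and 3, and 20 and 34 without mutant day 5 replicates 1 and 2; ins-7, mtl-1, hex-1 and clec-82 were the 4 of 23 named genes that kept their call throughout.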

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

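The tests against lower depth of the N2 libraries at day 5 and against different depth of the day 0 libraries were set before their results were seen; all other tests in this part, and the counts of other groupings, were chosen only after the result was seen.

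The change with age differed between the genotypes, by the test of that difference itself, for 93 genes, among them those named below. The lists below were called by camera with the preset correlation only. Each value is mutants minus N2 in log2. Among genes the difference was 4.34 for nlp-34, 2.8 for ttr-32, 2.61 for fipr-21, 2.6 for ttr-14, 2.58 for tatn-1, 2.52 for ins-7, 2.46 for tag-278, 2.32 for fip-5, 2.06 for col-140 and 2.04 for cex-1. It was -2.37 for mtl-2, -2.04 for asp-14, -1.95 for hex-1, -1.3 for gst-4 and -5.18 for mtl-1. List members added col-34 (1.49), ugt-29 (1.97), clec-82 (4.07), clec-232 (3.52), clec-147 (1.18), ins-4 (2.76), ins-8 (7.02) and math-41 (1.61). ins-8 and clec-82 averaged under 4 CPM in every group.

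List medians were 0.81 for cuticle collagens, 0.97 for major sperm proteins, -0.35 for germline and meiosis, -0.16 for DNA replication and cell cycle, -0.23 for mitochondrial stress, -0.0938 for DAF-16 induced genes and -0.15 for the proteasome. For body wall muscle the median was 0.83, for pharynx 1.03, for neuronal genes 0.70, for neuropeptides 0.35, for insulin-like peptides 0.34 and for other small RNA pathways -0.17. With other scaling or tools the direction held while sizes moved. Medians ran from -0.172 to -0.0191 for DAF-16 induced genes, -0.224 to -0.0717 for the proteasome, -0.231 to -0.0787 for DNA replication and -0.242 to -0.09 for other small RNA pathways. On the rlog values they were 0.29 for collagens, 0.37 for major sperm proteins, 0.49 for muscle, 0.50 for pharynx, 0.43 for neuronal genes, 0.22 for neuropeptides and 0.19 for insulin-like peptides. Each of these 13 camera calls had an adjusted p = 0.793 with an estimated correlation. With fry none of the 39 lists passed for this contrast (smallest adjusted p = 0.224).

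ppfr-1 and some features inside its intron, F16A11.5 foremost, were counted higher in the mutants. A shift of the whole neighbourhood is argued against by a median log2 difference of -0.0324 ± 0.0268 (SE) over 42 genes within 100 kb. An effect of the n4115 allele on transcripts of the locus stays open: F16A11.5 rose 2.08 ± 0.40 log2 more than ppfr-1. Reads of intron features counted to ppfr-1 stay open as well: the features' own mutant counts came to 0.744% of the rise of ppfr-1 counts, but reads given to ppfr-1 would be missing from them, and the read counter is not given in the sources used here. Whether the ppfr-1 protein changed was not analysed here.

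Muscle, pharynx, neuronal and collagen lists were higher in day 5 mutants by camera, and germline and meiosis, DNA replication and oocyte lists lower, each with an adjusted p = 0.777 with an estimated correlation. Sperm lists were not lower, after large falls with age in both genotypes. With all libraries thinned to the same depth the muscle median was 0.642, so unequal numbers of counts alone did not make it. Thinning keeps the expected share of each gene, so it could hardly move this median. Other traits of the shallower N2 libraries were not tested. The listed germline, sperm, oocyte, vitellogenin and collagen genes shifting the scaling are argued against, since without them in the factors the muscle median did not fall (0.667, and 0.649 with them); germline transcripts outside the lists were not tested. A lower share of germline RNA raising every somatic tissue alike cannot be told apart from changes within tissues: the 5 somatic medians (these and intestine) lay 0.457 apart, against interquartile ranges of 0.442 to 1.36. An effect of genotype on the tissues themselves stays open, untested.

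The day 0 libraries differed along an axis shared by both genotypes, with N2 replicate 1 and mutant replicates 1 and 3 on one side and with sperm, collagen, muscle and pharynx genes moving along it. Unequal numbers of counts alone did not make it, since 2486 genes were called between the sides at equal depth and 2897 at full depth. Thinning keeps the expected share of each gene, so other traits that go with the depth of these libraries were not tested. Cultures of different stage or age stay open: replicate 1 minus replicate 2 correlated across genes with the change with age of the other genotype at 0.541 in N2 and 0.599 in mutants. Handling shared by libraries of the same number stays open as well, with a lowest same-number correlation of 0.28 against 0.15 for the highest of the others.

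Among the groupings of the same libraries, the real one included, 1 of 10 had as many genes for the change with age in N2 (8729, highest other 0), 1 of 10 in mutants (8763, highest other 0) and 1 of 10 for genotype at day 5 (1798, highest other 0). For genotype at day 0 2 of 10 had as many (22, highest other 2897); the grouping with 2897 kept 2 of the 3 numbered pairs together, whereas the real one parted all 3. Groups of 3 give too few groupings for a share under 0.05. Every other grouping of 3 put libraries of both real groups on each side. A real difference then adds to the scatter within the sides and holds the count down. A highest other of 0 therefore gives no separate support. Groupings over both ages that mixed the genotypes at day 5 had the same limit. Averaged over both ages 2 of 100 had as many (874, highest other 3739), and for the difference between changes 3 of 100 (93, highest other 901). The grouping with 2897 genes is the one that defined the day 0 axis, so the axis gives no separate account of its count. The grouping with 3739 and 901 parted the day 0 libraries in the same way, and at day 5 it parted the genotypes as in reality. A further grouping with 215 genes for the difference, with N2 day 0 replicates 1 and 3 beside mutant day 0 replicate 2, also held the real genotypes at day 5, so neither was free of genotype.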

How the results depend on the processing

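The replicate block within each age, the block in day 0 libraries alone, thinning to equal depth, leaving out 2 day 0 libraries of the same number, the left-out libraries for correlations and for ppfr-1, and all settings for X chromosome genes were chosen after the data were seen; the other alternatives were planned. No named gene past the threshold reversed its direction, nor did a called list change direction with the scaling. Medians near 0 of lists not called did, such as germline and meiosis with age in N2 (0.12, and -0.0192 with upper-quartile factors). ppfr-1 averaged over both ages stayed past the threshold throughout, at a log2 of 1.3 (rlog) to 2.04. Calls of named genes that stayed in every setting were 132 of 138 with age in N2, 130 of 134 in mutants, 51 of 94 for genotype at day 5, 44 of 69 averaged over both ages and 4 of 23 for the difference between changes, and none of 3 at day 0. The cause of a moved count was not tested unless a smaller set of libraries or a stricter threshold made it. Depth limits low genes: 3 counts were up to 0.157 CPM. Seed matches of mir-71 were not run, as they need a genome sequence, nor were fits of single contrasts for the averaged comparison and the difference, which need all libraries.

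Threshold: with a fold of at least 2, 5350 genes passed with age in N2, 5438 in mutants, 1122 for genotype at day 5 and 421 averaged. At an adjusted p of 0.01 there were 7 at day 0, 553 at day 5, 276 averaged and 8 for the difference.

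Tool and filter: DESeq2 gave 62 genes at day 0, 2841 at day 5, 1720 averaged and 531 for the difference; for the difference no filter gave 245, limma-voom 32 and rlog values 162. Only the libraries of the contrast gave 0 at day 0 by edgeR (536 at an unadjusted p under 0.05; 62 by DESeq2 and 18 by voom with all libraries) and 2722 at day 5.

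Blocks: within each age they gave 73 at day 0, 3604 at day 5, 2455 averaged and 1045 for the difference. At day 5 the numbers did not pair the genotypes (same-number correlations of 0, -0.01 and 0.19). A block in day 0 libraries alone gave 60 at day 0, and a plain block 233 for the difference. Without both day 0 libraries numbered 1, 2 or 3 the day 0 count was 9, 13 or 0 (411 unadjusted for number 3); number 3 left 298 averaged and 7 for the difference, and number 2 left 234.

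Left-out libraries: counts ran from 7437 to 9234 with age in N2, 7614 to 8749 in mutants, 5 to 19 at day 0, 608 to 2389 at day 5, 455 to 1094 averaged and 9 to 463 for the difference.

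Lists and correlations: camera made 92 list calls over the 6 contrasts, of which 0 stayed with an estimated correlation. A block gave 98 calls, 91 of them shared, and left-out libraries 83 to 99. fry, which tests a list against no change and not against other genes, gave 60, with 42 shared. Of the fry calls, 22 were for age in N2, 28 for age in mutants, 7 for genotype at day 5 and 3 averaged. There were 0 for genotype at day 0 and 0 for the difference. The age correlation of 0.927 was 0.877 at a mean of at least 3 log2 CPM and 0.891 to 0.933 without single libraries. The genotype correlation of 0.252 was 0.254 at that level, 0.228 with a block and 0.0513 to 0.329 without single libraries.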

Other observations

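The 12 tests by chromosome in this part were chosen only after the result was seen. Genes higher in day 5 mutants were unevenly spread over chromosomes. Of 2304 tested genes on X, 343 were higher (14.9%, against 6.47% elsewhere; odds ratio 2.53, Fisher's exact test, adjusted p = 5.46e-37 over 12 tests), and 33 were lower (1.43% against 3.36%, adjusted p = 2.57e-07). The share of higher genes was 9.41% on V against 7.18% elsewhere (adjusted p = 4.52e-05), 4.78% on I against 8.16% (adjusted p = 1.2e-09) and 4.4% on III against 8.2% (adjusted p = 1.39e-11). On II and IV it was 6.49% against 7.87% (adjusted p = 0.0151) and 6.62% against 7.83% (adjusted p = 0.0356). Lower genes made up 4.02% on I against 2.92% elsewhere and 4% on IV against 2.91% (adjusted p = 0.00672 each); the tests of lower genes on II, III and V did not pass (adjusted p of 0.253 for III). Genes on a chromosome are not independent replicates. The excess of higher genes on X kept an odds ratio of 2.16 to 2.74 in every setting tried for X, with 13% against 5.63% under RLE factors. The stricter thresholds were not tried for X. The split of all genes moved from 1279 and 519 to 1113 and 825 under RLE factors. The shortage of lower genes on X was not past the threshold without N2 day 5 replicate 3 (unadjusted p = 0.791), mutant day 5 replicate 1 (0.785) or mutant day 5 replicate 3 (0.163). In the same comparison germline and meiosis genes had a median of -0.42, neuronal genes of 0.63 and muscle structure genes of 0.65 (adjusted p = 1.02e-08, 3.03e-08 and 3.71e-05; adjusted p = 0.777 with an estimated correlation for each). The X chromosome is known to hold few genes expressed in the germline, and the shares were not tested apart from the amounts of these tissues.

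Mitochondrial transcripts took 1.84% ± 0.27 of counts in N2 at day 0 and 0.945% ± 0.34 at day 5 (SD, n = 3), and 2.36% ± 0.88 and 0.911% ± 0.30 in mutants. Vitellogenin transcripts reached 14.9% in mutant day 5 replicate 3. Along the spread of the day 0 libraries, 24 of 81 ribosomal protein genes were lower, and of 204 F-box genes 31 were higher and 13 lower, in N2 replicate 1 and mutant replicates 1 and 3.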
